A study of Oryza sativa Indica Group with 11 samples.

How the data were processed

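Gene expression was measured in crown and growing point tissue of rice, dissected from several plants per sample, on an Affymetrix rice array with 1 biotin-labelled RNA sample per array. The 11 arrays fall into 4 groups: 3 of FL478 control plants, 3 of FL478 salt-stressed plants, 2 of IR29 control plants and 3 of IR29 salt-stressed plants. The salt dose, its duration and the age of the plants are not given in the labels used here. The labels call the arrays of a group biological replicates, so the p-values below measure variation between such samples, in 1 experiment.

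The deposited values are 1 signal intensity per probe set and array on a linear scale, which the authors made with GCOS 1.2 per the submitters' processing notes. The other steps, including the scanner settings and the expression algorithm, are not given in the sources used here. The trimmed mean over all probe sets was 500.1 on every array, so the values had been scaled per array. The table used here holds no detection calls. The number of arrays per group limits the precision of every value.

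The 123 control probe sets were left out, and the other 57258 of the 57381 probe sets were tested, with no filter on dim ones. Values were transformed as log2 of the intensity plus a pseudocount of 16. The array medians then differed by up to 0.47 on the log2 scale, above the limit of 0.1 set before the data were examined, so the arrays were quantile normalized. Between 24.4% and 30.4% of the probe sets lay under the pseudocount on each array. A log2 difference against a group that lies near the pseudocount depends on it.

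Each probe set was fitted with limma 3.58.1 in R 4.3.3 as 4 group means over all 11 arrays, with 7 residual degrees of freedom and a variance prior that follows the mean intensity. The 5 contrasts were salt against control in FL478, salt against control in IR29, the difference between these responses (IR29 minus FL478), and IR29 against FL478 in control and in salt-stressed plants. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all probe sets tested, and a probe set was called at an adjusted p under 0.05. Errors are standard errors from this fit. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

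Probe sets were joined to genes through the annotation table of the array. Exactly 1 gene was given for 22436 probe sets and several genes for 95, and 34727 were unnamed in the table. The probe sets with 1 gene stood for 17905 genes, all of which were found in the RefSeq gene table of the assembly ASM3414082v1. That assembly is not the build the array was designed on, so it served only for names and for which genes neighbour each other, and no coordinates are given. A symbol other than a locus number was available for 2452 genes with 3186 probe sets.

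Gene lists were fixed for 26 themes before the data were examined. The name patterns first written for them matched only 13 memberships, because the tables give symbols and few product names. The patterns of the same 26 lists were therefore rewritten as symbol patterns after the reference tables had been read and before any groups were compared, which gave 605 memberships. The lists are the flavonoid pathway, the phenylpropanoid and lignin pathway, cell wall, jasmonate synthesis and signalling, ABA with dehydrins and LEA proteins, stress transcription factors, sodium and potassium transport, proton pumps, aquaporins, antioxidant enzymes, class III peroxidases, glutathione S-transferases, heat shock proteins, defence proteins and proteinase inhibitors, osmolytes, sucrose and starch metabolism, gibberellin metabolism, auxin response, ethylene synthesis and ERF factors, nitrogen assimilation and nitrate transport, and cytosolic ribosomal proteins. Lists for tissues the dissection could hold are photosynthesis (leaf), DNA replication and cell cycle (dividing cells), KNOX and other shoot meristem genes (growing point), root-preferred genes, and xylem and secondary wall genes (vascular tissue). The flavonoid and cell wall lists were included because the published account of the study deals with them.

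Each gene was represented in the lists by its brightest probe set over all arrays. Lists with at least 5 measured genes, 22 of the 26, were compared with all other genes by camera in limma with a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The fry test, which asks whether the genes of a list move on balance in one direction, was run beside it. Single genes of a list were also adjusted over the list alone.

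Named genes follow a rule fixed before the data were examined. It takes the called genes with a descriptive name and the largest change in each direction, up to 10 for the salt responses and their difference and up to 5 for each comparison of the lines. In the salt responses every salt array also had to lie on one side of every control array. It adds up to 4 genes of each list with the smallest adjusted p in either salt response, and 12 genes given whatever their values. Of these 12, NHX1, SOS1, RCc3 and NCED3 were not named in the tables used here. Genes outside this rule are said to be chosen after their values were seen.

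The procedure was tested on simulated data, with changes added to 100 probe sets per contrast and size on the spread estimated by the fit. The changed probe sets were drawn only from those brighter than the median, so the recovery of dim ones was not tested. At a simulated log2 change of 1 it recovered 38% in the FL478 salt response, 25% in the IR29 salt response, 9% in their difference, 35% between the lines in control plants and 41% in salt-stressed plants. At a log2 change of 2 the shares were 79%, 74%, 54%, 78% and 91%, with 2 to 9 false calls per contrast. A list shifted by 0.4 was called in each of the 3 salt contrasts, with 0, 0 and 1 of the 21 other lists called. Each gene was simulated independently, so these counts do not show how many lists are falsely called when genes vary together.

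Alternatives fixed before the data were examined were the values as deposited, pseudocounts of 1 and 64, a filter on the 40% dimmest probe sets, a minimum change of 2-fold, the replicate number as a block, fits with only the groups compared, a variance prior without trend, array weights, probe sets without the suffixes that mark shared probes, and each of the 11 arrays left out in turn. For the lists they also included an estimated correlation, fry, and the mean of all probe sets of a gene. Array images and raw probe intensities were not used here.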

Results

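The arrays measured transcript levels in crown and growing point tissue of FL478 and IR29 rice, grown as controls or under salt. IR29 is a salt-sensitive indica cultivar, and FL478 is a salt-tolerant recombinant inbred line from the cross of IR29 with the tolerant landrace Pokkali. The groups hold 3 control and 3 salt arrays for FL478, and 2 control and 3 salt arrays for IR29. Every array had a trimmed mean intensity of 500.1, and the median intensity ran from 48.2 in FL478 control replicate 1 to 73.1 in IR29 control replicate 1. The number of arrays limits the precision of all values.

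The lines separated on the first principal component, which held 23.5% of the variance. FL478 arrays lay between -62.57 and -22.26 and IR29 arrays between 31.48 and 74.95, with IR29 control replicate 1 nearest to FL478. FL478 salt replicate 2 lay nearest to IR29, at -22.26, with the next FL478 array at -44.14. It also lay at -94.25 on the fourth component, which held 8.8% of the variance. On the second component, with 13.2% of the variance, IR29 control replicate 1 lay at -95.15 and FL478 control replicate 3 at -67.47. Whether IR29 control replicate 1 came from a mixed or off-type sample was not tested, and every IR29 salt response, every difference between the responses and every difference between the lines in control plants includes it. The log2 ratio of the 3' to the 5' probe set of cyclophilin, a sign of RNA quality, was 0.998 to 1.164 in the IR29 salt arrays against 0.707 and 0.907 in the IR29 controls. In FL478 it was 0.693 to 1.238 under salt and 0.411 to 0.880 in controls. The same ratio of actin was 0.658 to 0.786 in the IR29 salt arrays against 0.481 and 0.504 in the controls, while that of GAPDH overlapped (0.335 to 0.561 against 0.281 and 0.557). In FL478 the actin ratio was 0.696 to 1.034 under salt and 0.604 to 0.903 in controls.

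**Figure D1:**
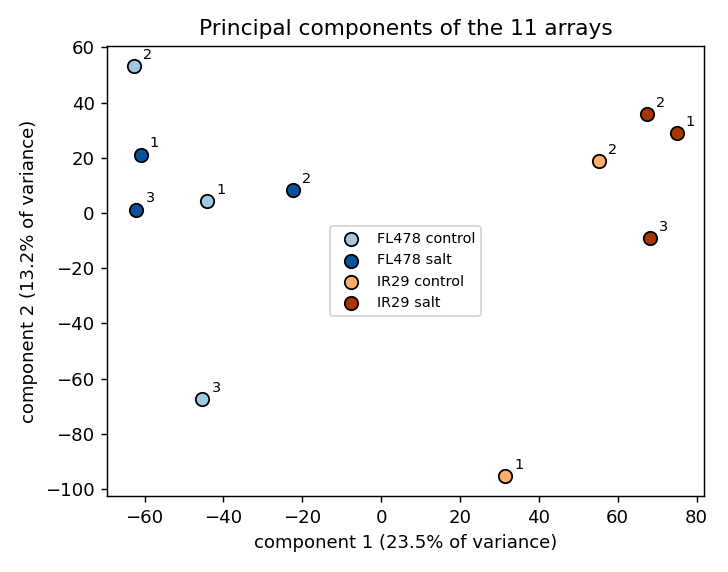
Each point is 1 of the 11 arrays, placed by its first (x axis) and second (y axis) principal component of the log2 values, coloured by group and numbered by replicate. FL478 arrays lie at or left of -22.26 and IR29 arrays at or right of 31.48, with IR29 control replicate 1 lowest on the second component at -95.15.

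The first comparison asked which transcripts differ between salt-stressed and control FL478. HKT1;5 (LOC4327757), the gene of a sodium transporter that retrieves sodium from the xylem sap, rose 5.63-fold, with a log2 change of 2.49 ± 0.31 (SE, n = 3 and 3, adjusted p = 0.0475). The dehydrin genes RAB16B, RAB16A and RAB16C, which respond to abscisic acid (ABA), had log2 changes of 2.07 ± 0.45, 1.81 ± 0.34 and 1.80 ± 0.34, and each rose when adjusted over the list alone. The list of ABA, dehydrin and LEA genes rose as a group, with 11 of 15 measured genes above 0 and a mean log2 change of 0.52 (adjusted p = 0.00126 by camera). The median change was only 0.215, so the 3 RAB16 genes carry much of that mean. The list held 3 genes called when adjusted over the list alone and 0 over all genes, and its mean was higher in every salt array than in every control array. The call was lost with an estimated correlation (adjusted p = 0.597 with an estimated correlation).

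In FL478, limma called 5 of 57258 probe sets, 4 higher and 1 lower under salt, against 3100 at an unadjusted p under 0.05. Besides HKT1;5, these have no symbol and were chosen after their values were seen. The largest change was at a probe set with no gene in the table, which rose 8.42-fold (log2 change 3.07 ± 0.29, adjusted p = 0.0107). LOC4339527 rose by 1.66 ± 0.18 (adjusted p = 0.0193), a further probe set without a gene by 1.88 ± 0.23 (adjusted p = 0.0475), and LOC4324999 fell by 1.02 ± 0.13 (adjusted p = 0.0475). In IR29 these last 2 had 0.88 ± 0.26 and -0.90 ± 0.14, with no call. The HKT1;5 call ended in 15 of 21 alternatives, with an adjusted p between 0.0278 and 0.303 and a log2 change between 2.11 and 2.68 over all of them. Leaving out any 1 array other than IR29 salt replicate 2 left 0 to 3 probe sets called and ended the HKT1;5 call.

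Antioxidant enzymes and heat shock proteins also rose as groups in FL478. Of 22 antioxidant genes 18 lay above 0, with a mean log2 change of 0.12 (adjusted p = 0.0192, and adjusted p = 0.237 with an estimated correlation). SODCC.2 and APX8, a superoxide dismutase and an ascorbate peroxidase gene, had values of 0.27 ± 0.13 and 0.26 ± 0.18, while the ascorbate peroxidase genes APX4 and APX5 had -0.11 ± 0.14 and -0.11 ± 0.73. Of 43 heat shock genes 26 lay above 0, with a mean of 0.17 (adjusted p = 0.0436, and adjusted p = 0.656 with an estimated correlation). Neither list had a gene called over all genes or over the list alone, where 3 and 4 genes were higher at an unadjusted p under 0.05 in limma, and both list means overlapped between the FL478 salt and control arrays. The antioxidant call ended without FL478 control replicate 1 (adjusted p = 0.115), FL478 control replicate 3 (adjusted p = 0.0593) or FL478 salt replicate 2 (adjusted p = 0.0977), and with the values as deposited (adjusted p = 0.213). The heat shock call ended without FL478 control replicates 1 or 3 (adjusted p = 0.386 and 0.146), FL478 salt replicate 3 (adjusted p = 0.367), or either of the IR29 controls (adjusted p = 0.0608 and 0.0598).

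The second comparison asked the same of IR29. Secondary wall genes of the xylem list rose together: all 6 lay above 0, with a mean log2 change of 0.76 (adjusted p = 1.7e-07). This was the 1 list in IR29 called with an estimated correlation (adjusted p = 0.0129 with an estimated correlation) and by fry (adjusted p = 0.000218). The cellulose synthase genes CESA4, CESA9 and CESA7, which make the cellulose of secondary walls, rose by log2 1.2 ± 0.18, 1.43 ± 0.24 and 0.86 ± 0.22 (n = 3 and 2). IRX9L, of a xylan synthesis family, rose by 0.47 ± 0.13, and these 4 calls are adjusted over the list alone. Over all genes none of the 6 was called by limma, where CESA4 had an adjusted p of 0.09 and CESA9 of 0.116, and 4 of 6 were higher at an unadjusted p under 0.05. The list mean, taken from its mean over all arrays, was -0.42 and -0.51 in the IR29 controls and 0.17 to 0.40 in the salt arrays, and it was called in all 17 alternatives. Of the 6 genes 3, CESA4, CESA7 and CESA9, are also on the cell wall list, which the published account prompted, so for them the rise is not independent evidence.

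ABA, dehydrin and LEA genes rose in IR29 as well, with 11 of 15 above 0 and a mean log2 change of 0.53 (adjusted p = 0.00242, and adjusted p = 0.336 with an estimated correlation). Over the list alone 5 genes were called, among them RAB16B (1.68 ± 0.50), rab25 (1.52 ± 0.47), RAB16C (1.25 ± 0.37) and ABA8OX2 (1.32 ± 0.29), which codes for an enzyme that breaks down ABA, and 0 over all genes. RAB16B lay near the pseudocount in the IR29 controls, at 5.31 and 5.40, so the size of its change depends on it. RAB16A had a value of 0.67 ± 0.39. In FL478 ABA8OX2 had 0.68 ± 0.26 and rab25 0.75 ± 0.42, with no call. Among the stress transcription factors, BZIP23, an ABA-responsive regulator, rose by 1.35 ± 0.17 and TRAB1 by 0.60 ± 0.16 when adjusted over the list alone, and BZIP23 by 0.69 ± 0.16 in FL478, where TRAB1 had 0.33 ± 0.15 with no call. Over all genes BZIP23 was called in IR29 in 5 of 21 alternatives, among them the values as deposited (adjusted p = 0.043), array weights (0.0481) and the fits without FL478 control replicates 2 or 3 (0.0491 and 0.0428), against 0.0739 with all arrays. That list was not called in IR29 (7 of 11 above 0, mean 0.23, adjusted p = 0.0699) or in FL478 (adjusted p = 0.994), where its mean of -0.12 and median of -0.25 lay below 0 and the test pointed up.

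DNA replication and cell cycle genes fell as a group in IR29, with 55 of 73 below 0 and a mean log2 change of -0.17 (adjusted p = 1.35e-05, and adjusted p = 0.336 with an estimated correlation). No single gene was called by limma over all genes or over the list alone, and 16 were lower and 1 higher at an unadjusted p under 0.05. The kinesin genes KIN14Q, KIN12C and KIN5C had values of -0.54 ± 0.15, -0.48 ± 0.13 and -0.47 ± 0.12, and the cyclin gene CYCA2-1 had -0.50 ± 0.15, against -0.33 ± 0.13 in FL478. In FL478 51 of 73 lay below 0, with a mean of -0.058 and no call (adjusted p = 0.117). Without FL478 control replicate 2 or FL478 salt replicate 3, or with the values as deposited, the list was called there (adjusted p = 0.028, 0.0436 and 0.0442). With the mean of all probe sets of a gene it was also called there (adjusted p = 0.0463).

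Phenylpropanoid and lignin genes rose in IR29, with 18 of 27 above 0 and a mean of 0.29 (adjusted p = 0.0154, and adjusted p = 0.336 with an estimated correlation). The 3 called over the list alone were PAL06 (1.44 ± 0.37), a gene of the entry step of the pathway, CAD2 (1.07 ± 0.20), of the last step to lignin monomers, and 4CL-3 (0.83 ± 0.24). Jasmonate genes rose, with 26 of 38 above 0 and a mean of 0.32 (adjusted p = 0.032, and adjusted p = 0.38 with an estimated correlation). No single one was called in limma over the list alone, and 3 were higher at an unadjusted p under 0.05. JAZ8 and JAZ7, repressors of jasmonate signalling, had values of 1.57 ± 0.59 and 1.06 ± 0.33, and AOS2 and AOC3, of jasmonate synthesis, 1.13 ± 0.54 and 0.90 ± 0.38. AOS2 lay near the pseudocount in both IR29 controls, and its change ranged from 0.54 to 1.81 over all alternatives. Sodium and potassium transport genes rose, with 19 of 28 above 0 and a mean of 0.29 (adjusted p = 0.0392, and adjusted p = 0.336 with an estimated correlation). HKT1;5 (2.22 ± 0.35) and the potassium transporter gene HAK22 (1.77 ± 0.38) were called over the list alone, and HKT1;5 had an adjusted p of 0.104 over all genes. Heat shock genes rose, with 30 of 43 above 0 and a mean of 0.27 (adjusted p = 0.0237, and adjusted p = 0.336 with an estimated correlation), and HSP17.9B rose by 0.98 ± 0.23 over the list alone.

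The flavonoid list, which the published account prompted and which is not independent evidence, held 2 measured genes and no set test. In IR29 both rose when adjusted over the list alone and neither over all genes. CHS1, chalcone synthase of the first step of the pathway, rose by 2.32 ± 0.32 (4.99-fold) and CHI by 1.21 ± 0.30. Over all genes CHS1 had an adjusted p of 0.0863, and of 0.0166 without IR29 salt replicate 3. In FL478 they had values of 0.073 ± 0.29 and 0.30 ± 0.27, with no call. The other 4 CHS1 probe sets, each dimmer than this one, had IR29 values from -0.13 to 1.16. The cell wall list, likewise not independent evidence, was not called in IR29 (44 of 77 above 0, mean 0.040, adjusted p = 0.516) or in FL478 (30 of 77 above 0, mean -0.088, adjusted p = 0.236), where its mean was lower in every salt array than in every control. In IR29 5 of its genes were called over the list alone and 0 over all genes: CESA3 (0.53 ± 0.12) with CESA4, CESA7 and CESA9 higher, and the expansin gene EXPB2 lower (-2.46 ± 0.62). EXPB2 was 6.70, 4.62 and 4.63 in the IR29 salt arrays, of which the last 2 lie near the pseudocount and are not shown to exceed background, and its change ranged from -3.33 to -1.52 over all alternatives. In FL478 EXPB2 had a value of -2.35 ± 0.56, without a call but with every salt array below every control, and the difference was -0.11 ± 0.84. Its FL478 salt values of 5.63, 4.94 and 5.65 were also low, so the sizes of this change and of the difference depend on the pseudocount.

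Limma called 3 of 57258 probe sets in IR29, each higher under salt, against 4220 at an unadjusted p under 0.05. All were chosen after their values were seen. The probe set with the largest change in FL478 rose 8.97-fold (log2 change 3.17 ± 0.32, adjusted p = 0.0252). LOC4339527 rose by 1.65 ± 0.20 (adjusted p = 0.0451) and LOC4349605 by 2.26 ± 0.25 (adjusted p = 0.0252). Without IR29 salt replicate 1 or 2, 0 of these 3 probe sets were still called, and LOC4339527 had adjusted p values of 0.412 and 0.121. Without IR29 control replicate 2 the count was 65, of which 50 were lower, while it was 1 without FL478 salt replicate 1, IR29 control replicate 1 or IR29 salt replicate 2 and 0 without IR29 salt replicate 1. In IR29 10 lists were called without IR29 control replicate 1. Without IR29 control replicate 2 xylem was the 1 list called, and the other 6 had adjusted p values of 0.252 to 0.427. Without IR29 salt replicate 3 the phenylpropanoid (adjusted p = 0.12), jasmonate (0.0866), ABA (0.0501) and heat shock (0.169) calls ended. Without IR29 salt replicate 1 those of jasmonate (0.0668) and transport (0.0525) ended, and without IR29 salt replicate 2 that of transport (0.13). The jasmonate call also ended with the values as deposited (0.0774), and the jasmonate and transport calls with the mean of all probe sets of a gene (0.0501 for both). The cyclophilin and actin ratios were higher in the IR29 salt arrays than in both IR29 controls, as were the means of the xylem, ABA, jasmonate, transport and heat shock lists. Cell cycle means were lower in every IR29 salt array, and phenylpropanoid means overlapped.

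**Figure D2:**
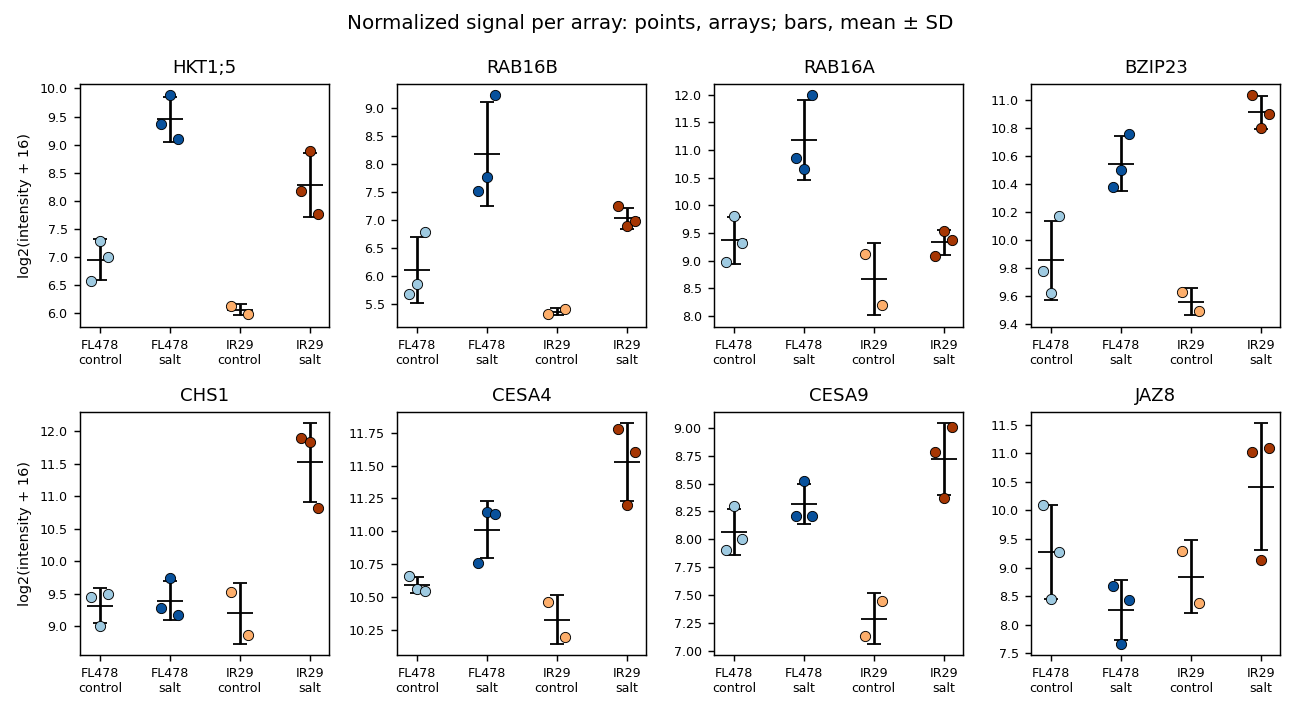
Each panel shows 1 gene, with a point per array on the y axis (log2 of the normalized intensity plus 16), the 4 groups on the x axis and the group mean and SD drawn beside them. HKT1;5 is higher in every salt array than in every control array of the same line, and CHS1 and CESA9 separate the IR29 groups while their FL478 groups overlap.

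The other lists were not called in either line with all arrays and the main settings. Osmolyte genes had 8 of 13 above 0 in IR29 (mean 0.38, adjusted p = 0.0699, called without IR29 control replicate 1 or IR29 salt replicate 2 with 0.0351 and 0.00695) and 6 of 13 in FL478 (adjusted p = 0.698). P5CS2, of proline synthesis, rose by 1.77 ± 0.58 and the trehalose phosphatase genes TPP3 and TPP10 by 1.58 ± 0.39 and 1.18 ± 0.39 in IR29, all 3 over the list alone. P5CS2 had a value of 1.66 ± 0.52 in FL478, without a call, and the difference was 0.12 ± 0.78. TPP3 lay near the pseudocount in both IR29 controls and is not shown to exceed background there, and its change ranged from 0.67 to 3.21 over all alternatives. P5CS1 had 0.34 ± 0.11 in FL478 and 0.15 ± 0.12 in IR29. Of 29 sucrose and starch genes, the invertase gene CIN2 fell by 1.24 ± 0.26 in FL478 and by 1.62 ± 0.29 in IR29 over the list alone. The list had adjusted p values of 0.698 and 0.876, with 2 and 1 genes called over the list alone, and its IR29 mean of -0.010 had the opposite sign to its median and test. Over the list alone in IR29, 1 of 58 auxin genes rose (IAA2, 0.89 ± 0.19), as did 1 of 13 ethylene genes (EIL1, 0.55 ± 0.14), and 1 of 18 nitrogen genes fell (GLN1-2, -0.72 ± 0.17, against -0.37 ± 0.16 in FL478). None of these 3 lists had a gene called over the list alone in FL478, and none was called as a group, with adjusted p values of 0.477, 0.767 and 0.6 in FL478 and 0.701, 0.867 and 0.902 in IR29. The mean of the auxin list was lower in every FL478 salt array than in every FL478 control.

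Defence genes had 23 of 33 above 0 in IR29 (mean 0.25, adjusted p = 0.0658, called without FL478 control replicate 1 or IR29 salt replicate 3 with 0.0356 and 0.00872) and 15 of 33 in FL478 (adjusted p = 0.6). Aquaporins had 6 of 25 above 0 in IR29 (adjusted p = 0.673) and 9 of 25 in FL478 (adjusted p = 0.474), where PIP1-3 had 1.5 ± 0.56 and 1.16 ± 0.51. In IR29 and FL478, adjusted p values were 0.541 and 0.333 for 6 glutathione S-transferases, 0.701 and 0.698 for 13 gibberellin genes, and 0.286 and 0.698 for 21 cytosolic ribosomal protein genes. The ribosomal genes were called lower in IR29 without IR29 control replicate 1 (0.0284) and in FL478 with the values as deposited (0.00405). Photosynthesis genes, markers of leaf, had 0.272 and 0.836, and the list was called in IR29 without IR29 control replicate 1 or IR29 salt replicate 2 (0.000684 and 0.0177). The mean of the photosynthesis list ranged by 0.722 among FL478 controls, 0.439 among FL478 salt arrays, 0.787 between the IR29 controls and 0.687 among IR29 salt arrays. These ranges exceed its shifts after salt, 0.131 in IR29 and -0.021 in FL478. The antioxidant list was not called in IR29 (adjusted p = 0.701), where its mean of -0.044 lay below 0 and its median and test above. KNOX and other shoot meristem genes, markers of the growing point, had adjusted p values of 0.701 in IR29 and 0.477 in FL478. Their IR29 median was -0.056, with a mean of 0.072 and a test above 0, and OSH1 had -0.15 ± 0.20 and -0.13 ± 0.18. Lists too small for a set test had no gene called: 3 class III peroxidases (mean 0.079 in IR29, -0.26 in FL478), 3 root-preferred genes (-0.15 and -0.44) and 1 proton pump gene, VATP-P1 (0.052 and 0.019). SalT had -0.60 ± 0.21 in IR29 and -0.36 ± 0.19 in FL478, and LEA19, the LEA3 gene, 0.36 ± 0.59 and 0.050 ± 0.52, with no call and most of its arrays near the pseudocount.

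The third comparison tested whether the salt response differs between the lines. Xylem and secondary wall genes rose more in IR29, where all 6 had a larger change, by a mean of 0.61 on the log2 scale (adjusted p = 3.09e-05). The call held with an estimated correlation (adjusted p = 0.0366 with an estimated correlation) and by fry (adjusted p = 0.00543). CESA9 differed by 1.19 ± 0.32 and CESA4 by 0.78 ± 0.24, both called over the list alone and neither over all genes, and the list was not called in FL478 (4 of 6 above 0, mean 0.15, adjusted p = 0.333). Its mean was nonetheless higher in every FL478 salt array than in every FL478 control, and CESA4 (0.42 ± 0.16) and CESA7 (0.46 ± 0.20) were higher there at an unadjusted p under 0.05 in limma. The xylem list mean was -0.42 and -0.51 in the IR29 controls, against -0.10 to -0.03 in the FL478 controls. Under salt it was 0.17 to 0.40 in IR29 and 0.03 to 0.13 in FL478. The lines thus lay further apart in controls than under salt, and a lower level in the 2 IR29 controls made up much of the difference. Jasmonate genes differed by a mean of 0.58, with 28 of 38 above 0 (adjusted p = 0.00199), and phenylpropanoid genes by 0.36, with 21 of 27 above 0 (adjusted p = 0.0035). Transport genes differed by 0.36, with 21 of 28 above 0 (adjusted p = 0.0158), and defence genes by 0.33, with 26 of 33 above 0 (adjusted p = 0.0438). Each of these 4 lists had an adjusted p of 0.293 with an estimated correlation. Cell cycle genes differed by -0.11, with 51 of 73 below 0 (adjusted p = 0.0158, and adjusted p = 0.58 with an estimated correlation).

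PAL06 was the phenylpropanoid gene called over the list alone, with a difference of 1.99 ± 0.50 and a FL478 value of -0.55 ± 0.33, and the list had 11 of 27 above 0 in FL478 (mean -0.072, adjusted p = 0.505). Jasmonate, transport, defence and cell cycle had 0 genes called by limma over the list alone, against 6, 2, 2 and 0 higher and 1, 0, 0 and 5 lower at an unadjusted p under 0.05. JAZ8 differed by 2.58 ± 0.79, with -1.01 ± 0.53 in FL478, where 27 of 38 jasmonate genes lay below 0 (mean -0.27, adjusted p = 0.0917). The jasmonate list was called in FL478 without FL478 salt replicate 1 (0.00997) or without the 40% dimmest probe sets (0.00956). HAK22 differed by 1.73 ± 0.50 and FL478 transport genes had 10 of 28 above 0 (mean -0.077, adjusted p = 0.477). The chitinase gene Cht2 differed by 2.54 ± 0.64, from 1.34 to 4.03 over all alternatives, and its FL478 salt values of 4.28 to 5.13 lie near the pseudocount and are not shown to exceed background. Both flavonoid genes differed over the list alone, CHS1 by 2.24 ± 0.43 and CHI by 0.91 ± 0.41, which is not independent evidence, and neither did over all genes. TPP3 (2.27 ± 0.52, from 0.94 to 4.68 over all alternatives) and IAA2 (1.46 ± 0.26) differed over their lists alone, and IAA2 was lower in every FL478 salt array than in every control and higher in every IR29 salt array. ABA, dehydrin and LEA genes differed by a mean of 0.006 (adjusted p = 0.919), with RAB16A at -1.14 ± 0.52 and HKT1;5 at -0.27 ± 0.47, neither called.

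Of the other lists none was called in the difference with all arrays and the main settings. The cell wall list had an adjusted p of 0.0547 and was called without FL478 control replicate 2, IR29 control replicate 1 or IR29 salt replicate 2 (0.0366, 0.0129 and 0.0113). Without the 40% dimmest probe sets the cell wall list was called as well (0.0159). The stress transcription factors had 0.0761, and 0.0414 without FL478 control replicate 3. The photosynthesis list had 0.389, and was called without FL478 control replicate 2 or IR29 control replicate 1 (0.0366 and 0.00374). Adjusted p values were 0.226 for antioxidant enzymes, 0.821 for heat shock, 0.325 for osmolytes and for KNOX genes and 0.366 for auxin. They were 0.604 for ribosomal proteins, 0.785 for nitrogen, 0.933 for ethylene, 0.971 for gibberellin, and 0.919 for aquaporins, glutathione S-transferases and sucrose and starch. Class III peroxidases, root-preferred genes and the proton pump gene had mean differences of 0.33, 0.29 and 0.033 and no call. Signs were mixed for heat shock (median -0.034, mean 0.11, test up), gibberellin (-0.074, 0.021, up) and ethylene (-0.072, -0.14, up). In FL478 they were mixed for osmolytes (median -0.033, mean 0.058, test up), photosynthesis (0.045, -0.021, up) and ethylene (0.029, 0.014, down).

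No probe set was called by limma in the difference, against 3059 at an unadjusted p under 0.05. Over all 57258 probe sets the log2 changes of the lines had a Pearson r of 0.036, where probe sets are not independent replicates. LOC4339527 and the probe set with the largest change were called as higher in both lines, which is 2 probe sets against 0.00021 if the calls were independent (Fisher's exact test, p = 1.1e-08). Both responses use the same estimate of spread for each probe set, so the calls are not independent. This p therefore does not measure a shared response. With only the 2 groups compared the overlap was 0. Without IR29 control replicate 2 the difference had 21 calls, all lower, and of the 6 lists only xylem was called, the others having adjusted p values of 0.162 to 0.705. The transport call also ended without FL478 control, FL478 salt or IR29 salt replicate 2 (0.0933, 0.064 and 0.0643). The cell cycle call ended without FL478 control replicate 2, FL478 salt replicate 3 or IR29 salt replicate 1 (0.105, 0.103 and 0.0719). The defence call ended in 12 of 17 alternatives, including those without FL478 control replicates 2 or 3 (0.0933 and 0.172), FL478 salt replicates 1 or 3 (0.112 and 0.0773), IR29 control replicate 1 (0.0771) or IR29 salt replicates 1 or 2 (0.415 and 0.0611), and with the values as deposited (0.166). With the mean of all probe sets of a gene the transport, cell cycle and defence calls ended (0.0729, 0.0537 and 0.13).

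**Figure D3:**
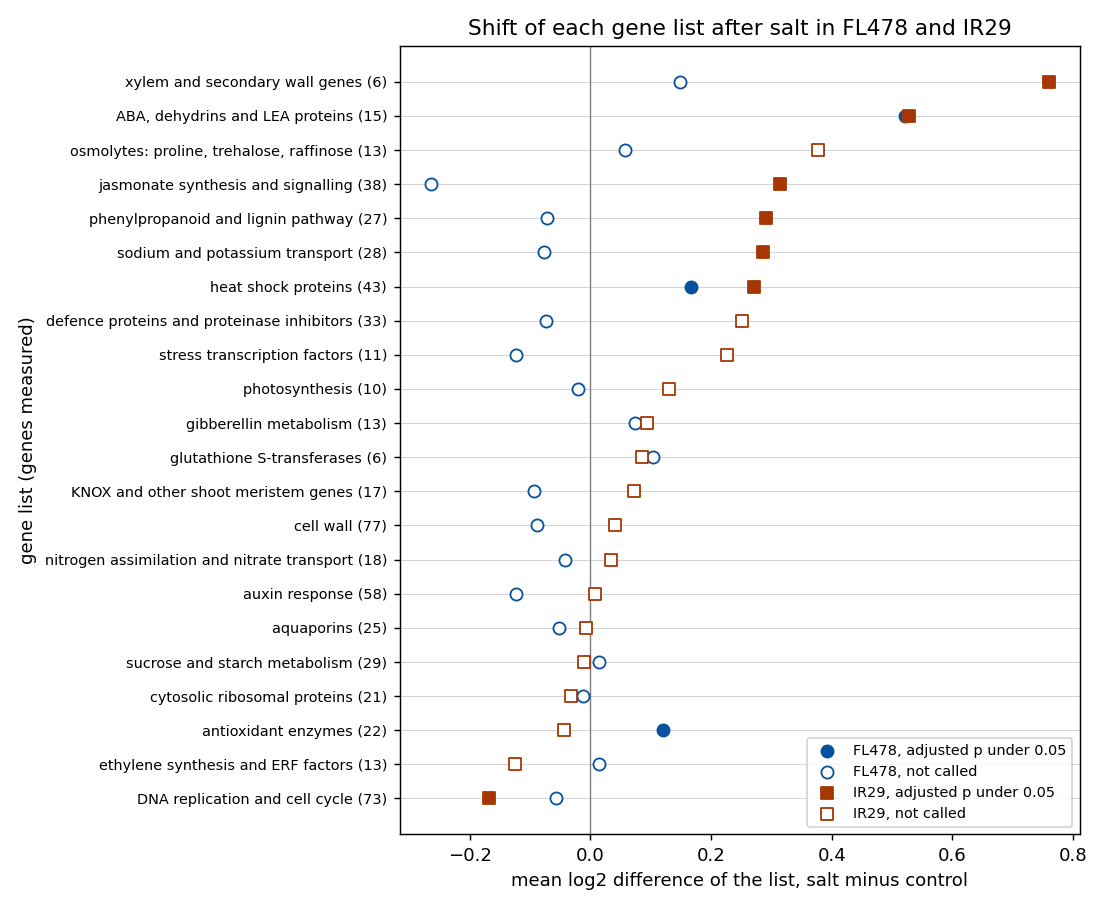
Each line of the y axis is a gene list with its number of measured genes, and points give the mean log2 change of the list after salt (x axis) in FL478 and IR29. The xylem list stands at 0.15 in FL478 and 0.76 in IR29, and the ABA list at 0.52 and 0.53.

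The remaining comparisons asked how the lines differ without and with salt. In control plants limma called 466 probe sets, 205 higher and 261 lower in IR29, of which 246 have 1 gene in the table and stand for 230 genes. VDAC1, of a mitochondrial outer membrane channel, was higher in IR29 by a log2 difference of 3.54 (11.6-fold, adjusted p = 0.000365). MDP1, of a MADS-box factor, was higher by 2.94 (adjusted p = 0.000123) and BAK1-7, of a receptor kinase, by 1.44 (adjusted p = 0.0217). PROLM25, of a seed storage prolamin, had a difference of -3.37 (adjusted p = 0.00653), SPO11-4 of -2.81 (adjusted p = 8.8e-06), and RAD23 of -2.27 (adjusted p = 0.0059). DREB1E, of a stress transcription factor, had -2.22 (adjusted p = 0.0392) and Rictpi2 -1.94 (adjusted p = 0.000388). PROLM25 lay near the pseudocount in every IR29 array and is not shown to exceed background there, and its difference ranged from -4.63 to -2.07 over all alternatives. Standard errors of these 8 genes ran from 0.18 to 0.50 (n = 2 and 3). The DREB1E difference ranged from -3.02 to -1.32 over all alternatives, with IR29 control replicate 1 near the pseudocount at 4.65. Its call ended in 13 of 21 alternatives, with an adjusted p of up to 0.277, and leaving out any 1 of 9 arrays ended it. The count was 286 without FL478 control replicate 1, 306 without FL478 control replicate 2 and 267 without IR29 control replicate 2. It was 367 without IR29 control replicate 1, and 265 of the 466 were among these. BAK1-7, PROLM25 and RAD23 were no longer called without IR29 control replicate 2 (adjusted p = 0.131, 0.0611 and 0.0666). BAK1-7 was also not called without FL478 control replicate 1 or IR29 control replicate 1 (adjusted p = 0.0716 and 0.136).

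In salt-stressed plants 992 probe sets were called, 472 higher and 520 lower in IR29, of which 558 have 1 gene in the table and stand for 510 genes. APX5, an ascorbate peroxidase gene, was lower in IR29, with a log2 difference of -4.96 ± 0.73 (n = 3 and 3, adjusted p = 0.00319). Its IR29 salt values of 4.32 to 5.47 lie near the pseudocount and are not shown to exceed background, so the size depends on it, from -6.07 to -3.68 over all alternatives. It was not called in control plants (-2.78, adjusted p = 0.217), where its IR29 values were 9.27 in replicate 1 and 5.28 in replicate 2, against 9.77 to 10.40 in FL478. Without IR29 control replicate 2, APX5 was called lower after salt in IR29 (-4.27, adjusted p = 0.00337) and in the difference between the responses (-4.16, adjusted p = 0.0249), against -2.29 ± 0.81 and -2.18 ± 1.09 with all arrays. SPO11-4, Rictpi2, RAD23 and PROLM25 were again lower in IR29, with differences of -2.90, -2.54, -2.70 and -2.78 (-4.41 to -1.51 for PROLM25 over all alternatives), and VDAC1 and MDP1 again higher, by 3.85 and 3.07. RBBI3.3, of a Bowman-Birk proteinase inhibitor (4.12 ± 0.84, adjusted p = 0.0278), pinA (3.98 ± 0.84, adjusted p = 0.0327) and the laccase gene LAC20 (2.79 ± 0.59, adjusted p = 0.0325) were higher. Each of these 3 calls ended without any 1 of FL478 salt replicates 1 and 3 or the 3 IR29 salt arrays, and that of pinA without either IR29 control, with adjusted p values up to 0.163. All 3 also ended with a variance prior without trend (0.0852, 0.0955 and 0.0785), and that of LAC20 with a pseudocount of 1 (0.164). RBBI3.3 and pinA had nearly the same values in the FL478 salt arrays, 7.44, 10.67 and 7.50 against 7.14, 10.64 and 7.69. They were also close in the IR29 salt arrays, 13.14, 12.26 and 12.59 against 12.98, 12.07 and 12.35. The RBBI3.3 probe set carries a suffix that marks shared probes, as do those of VDAC1 and PROLM25. Whether the RBBI3.3 probe set shares probes with that of pinA was not tested, so RBBI3.3 and pinA may not be separate measurements. Among genes named with the salt responses, CHS1 was higher in IR29 by 2.13 ± 0.29 (adjusted p = 0.0018), HAK22 by 1.87 ± 0.34 (adjusted p = 0.0126) and CHI by 1.2 ± 0.27 (adjusted p = 0.0483). RAB16A was lower, at -1.85 ± 0.34 (adjusted p = 0.016). The count was 548 without FL478 salt replicate 1, 579 without FL478 salt replicate 3, 543 without IR29 salt replicate 1 and 655 without IR29 salt replicate 3. It was 1279 without FL478 salt replicate 2, the FL478 array nearest to IR29 on the first principal component.

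Of the 466 probe sets called between the lines in control plants and the 992 called under salt, 384 were called in both in the same direction and 0 in opposite directions, and 458 of the 466 control calls had the same sign under salt. The called genes were spread unevenly, from 1.71% of the measured genes of chromosome 6 to 6.06% of those of chromosome 12 in salt-stressed plants, and in control plants chromosome 12 again had the highest share, 2.97%.

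**Figure D4:**
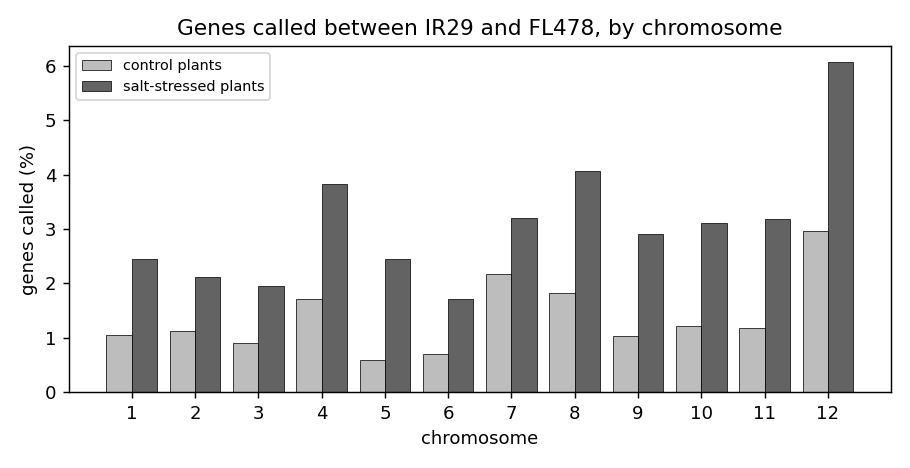
Bars give the percent of measured genes called between IR29 and FL478 (y axis, from 0) on each of the 12 rice chromosomes (x axis), in control and in salt-stressed plants. Chromosome 12 has the highest share in both, 2.97% and 6.06%.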

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

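The test on meristem genes was chosen only after the result was seen, and the other tests were fixed before their results. The results here are the 6 gene lists whose salt response differed between IR29 and FL478 in a test of the difference itself. Of these only xylem was called with an estimated correlation, by fry, or when IR29 control replicate 2 was left out. Besides the lists weighed here, transport (adjusted p = 0.0158), cell cycle (adjusted p = 0.0158), defence (adjusted p = 0.0438) and phenylpropanoid genes (adjusted p = 0.0035) differed.

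Xylem and secondary wall genes responded more strongly in IR29 (adjusted p = 3.09e-05). If 1 of the IR29 controls set the difference, the call would end without it, but without either one or the other the higher adjusted p was 0.0129, which argues against a single control array. Leaving out 1 control cannot address a low level in both IR29 controls, -0.42 and -0.51 against -0.10 to -0.03 in the FL478 controls. A smaller share of growing point in the dissected salt samples of IR29 could also raise vascular genes. Meristem genes were not called lower there (adjusted p = 0.701 by camera), which decides nothing because their median of -0.056 lay near 0 with members on both sides. Genes of dividing cells fell (adjusted p = 1.35e-05 by camera, and 0.336 with an estimated correlation), as less growing point or less division in it would both give. That fall leans on IR29 control replicate 2, with a list mean of 0.165. IR29 control replicate 1 lay at -0.032, close to the highest IR29 salt array at -0.039. Leaf markers varied within groups, with photosynthesis list means of 0.381 and -0.406 in the IR29 controls. Whether the share of leaf tissue differed between the dissected samples was not tested. A different response of IR29, the biological explanation the design offers, stays open and cannot be told apart from a difference in dissection.

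Jasmonate genes responded differently in the lines (adjusted p = 0.00199), by a mean of 0.58 on the log2 scale, with no call with an estimated correlation (adjusted p = 0.293), by fry (adjusted p = 0.253) or without IR29 control replicate 2 (adjusted p = 0.162). The mean of this list ranged by 0.659 among the 3 FL478 control arrays, where replicate 1 lay at 0.593 and replicates 2 and 3 at -0.066 and -0.057. Arrays of 1 group therefore differ by as much as the responses do, which is consistent with variation between samples as a source of part of the difference. The IR29 part of it, with every salt array above both controls, does not rest on that group. A response that truly differs between the lines remains open as well.

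IR29 and FL478 differed at 992 probe sets under salt, where sequence variants under the probes could make single probe sets differ without a difference in transcript. Among 64 other bright probe sets, from 54 of the 510 called genes, 29.7% showed the same direction at an unadjusted p under 0.05 in limma. At any p, 46 of the 64 had the same sign. For genes not called the share was 1.7%, which is lowered because the probe set with the smallest p of each gene was set aside. The 29.7% lies between the values either explanation predicts, which leaves both open. Most called genes had no such other probe set and were not covered. Called genes had another called gene among the 5 measured genes on each side in 47.6% of cases, against at most 31.4% in 1000 random draws. They thus lie near each other along the chromosomes more often than randomly drawn genes. Neighbours could also move together in any comparison. As many genes ranked by the salt response of IR29 gave 29.4%, against a median of 24.9% in the random draws. That response had only 3 called probe sets, so its ranking is too weak to decide, and this explanation stays open. Segments where FL478 carries the other parent's sequence could give such clustering, but the parent of a segment was not tested.

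Other splits of the 6 FL478 arrays were too few, at 10, for a share under 0.05. The real split called 5 probe sets and the highest other 11, so 2 splits gave as many or more, and the split with 11 set FL478 control replicates 1 and 3 and FL478 salt replicate 2 against the rest. For gene lists the real split called 3 and the highest other 3, again 2 splits. The other splits called 2, 1, 0, 3, 1, 2, 0, 2 and 0 lists. Lists were thus also called with salt and control arrays mixed, so the number called in FL478 does not by itself show a salt response. For the salt-stressed plants of both lines the 10 splits are also too few: the real one called 992 probe sets and the highest other 0, so 1 split gave as many.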

How the results depend on the processing

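All alternatives here were fixed before the data were examined. No result reversed its direction past the threshold. Over all alternatives 117 counts stayed within 1.5 times their value and 59 did not, 6704 values of single genes kept their side of the threshold while 123 lost and 10 gained a call, and for single lists 1022 kept it, 76 lost and 24 gained a call. Most of these genes and lists were not called with the main settings and had no call to lose. The totals therefore do not measure how stable the calls are.

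The FL478 salt response had 5 calls, against 8 with a pseudocount of 1, 2 with 64, 8 without the 40% dimmest probe sets, 1 with a variance prior without trend and 2 with array weights. The IR29 salt response had 3, against 6 with a pseudocount of 64 and 5 with array weights. With only the 2 groups compared both had 0, the overlap of 2 was 0 and the control-plant difference between the lines 150 instead of 466, where fewer arrays leave fewer degrees of freedom. The overlap was also 0 without the trend, where 0 of the 5 FL478 calls and 0 of the 3 IR29 calls were kept. The difference in salt-stressed plants was 1660 instead of 992 with array weights. The dim filter tests fewer probe sets, and for the other settings the cause was not tested.

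With the replicate number as a block the counts were 7 in FL478, 14 in IR29, 0 in the difference, 381 and 939 between the lines, 3 in the overlap, and 4, 7 and 7 lists. The labels do not say that equal numbers pair arrays, and the residuals of equally numbered arrays of a line correlated by -0.051 to 0.058; the cause of the rise to 14 was not tested. With the block, HKT1;5 (adjusted p = 0.0469), CHS1 (0.0469), BZIP23 (0.0464) and the stress transcription factors (0.0469) were called in IR29, the last also in the difference (0.0456), and jasmonate genes in FL478 (0.0129). The calls of heat shock in IR29 (0.0824), LOC4324999 in FL478 (0.0901) and DREB1E in control plants (0.0505) ended.

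Lists called were 3 in FL478, 7 in IR29 and 6 in the difference. They were 0, 1 and 1 with an estimated correlation and 0, 1 and 1 with fry, both of which let the genes of a list vary together, and the difference had 3 with the mean of all probe sets of a gene.

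Leaving out 1 array gave 0 to 4 calls in FL478, 0 to 65 in IR29, 0 to 21 in the difference, 267 to 525 in control plants, 543 to 1279 in salt-stressed plants, 0 to 2 in the overlap, and 1 to 4, 1 to 10 and 1 to 7 lists. Without 1 IR29 control the lone one is assumed to vary like the other groups, and the cause of the high counts without IR29 control replicate 2 was not tested. Signal over background limits dim genes, with up to 30.4% of probe sets under the pseudocount.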

Other observations

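The values in this part were all chosen after the data were examined. Over the 992 probe sets called between the lines under salt, IR29 control replicate 1 lay nearer to FL478 than the other IR29 control. On a scale from 0 at the mean of the FL478 salt arrays to 1 at the mean of the IR29 salt arrays, over the 992 probe sets called between them, its median position was 0.72 and that of IR29 control replicate 2 was 0.94. FL478 control arrays had medians of 0.030, -0.020 and 0.090. The position of IR29 control replicate 1 was 0.69 for probe sets higher in IR29 and 0.74 for those lower, with quartiles of 0.43 and 0.94. APX5 is an example, at 9.27 in that array, 5.28 in IR29 control replicate 2 and 4.32 to 5.47 in the IR29 salt arrays. Over all probe sets IR29 control replicate 1 correlated less than IR29 control replicate 2 with every FL478 array and IR29 salt array except FL478 control replicate 3. A lower r with both lines does not by itself show which line an array is nearer to. The Pearson r of IR29 control replicate 1 with the FL478 salt arrays was 0.9524, 0.9575 and 0.9531, against 0.9563, 0.9603 and 0.9544 for IR29 control replicate 2. With the FL478 controls it was 0.9537, 0.9474 and 0.958, against 0.9576, 0.9563 and 0.9538. With the IR29 salt arrays it was 0.9569 to 0.9617, against 0.9681 to 0.9699. Its values with FL478 control replicate 3 and FL478 salt replicate 2 thus lay above its lowest value with the IR29 salt arrays. For IR29 control replicate 2 no FL478 value did so. On the first principal component, also over all probe sets, IR29 control replicate 1 was the IR29 array nearest to FL478, at 31.48. The position of a control array was not used to call the probe sets, beyond the shared estimate of spread. Whether the sample was mixed or off-type was not tested, so the IR29 salt responses, their difference from FL478 and the difference between the lines in control plants carry that doubt.

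Genes that differ between the lines under salt include several of known traits. IPA1, which shapes tillers and panicles, was lower in IR29 by a difference of -1.33 ± 0.20 (n = 3 and 3, adjusted p = 0.00344 in limma), and was also lower in control plants (-1.16 ± 0.22, adjusted p = 0.0325). NRAMP5, a manganese and cadmium transporter gene, had -1.09 ± 0.16 (adjusted p = 0.00282) and -0.88 ± 0.18 in control plants (adjusted p = 0.0414). BADH1, a betaine aldehyde dehydrogenase gene, had -0.98 ± 0.18 (adjusted p = 0.0148) and -0.61 ± 0.20 in control plants, without a call (adjusted p = 0.32).

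The densest stretch of called genes lay on chromosome 8, where 13 of 40 consecutive measured genes were called between the lines under salt, 10 higher and 3 lower in IR29. The highest number in random draws was 10. The next densest stretches, on chromosomes 1, 7 and 9, held 9, 8 and 8 called genes and did not exceed it. GL2-1 is the 1 gene with a symbol among the 13 called on chromosome 8.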
